A study of Penicillium oxalicum with 6 samples.

How the data were processed

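RNA was sequenced from mycelium of the filamentous fungus Penicillium oxalicum after 24 h in liquid medium with 1% Avicel, a microcrystalline cellulose. A mycelium amount of 1 g is given for every library. The strain labels were MuPOX06509 for 3 libraries and Ku70 for 3. They are read here as a POX06509 deletion mutant and a Ku70 mutant. The letters F, S and T in the titles told the libraries of each group apart. Ku70 is a protein of non-homologous end joining, and fungal strains without it are commonly used as hosts for targeted gene deletion. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

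The authors deposited an expected count and an FPKM (fragment count scaled to gene length and library size) for each of 9834 gene IDs in each library, per the file headers. An expected count is an estimate in which reads that fit several genes are divided between them, so it need not be whole; 457 genes had a fractional expected count in at least 1 deposited library, and these genes are less certain. The submitters' processing notes name RSEM 1.2.12, Bowtie2 2.1.0, BWA 0.7.10-r789 and DESeq2, with no role or order. The genome build, the annotation and any strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated. FPKM of a gene is relative to all other genes of its library, and a change in a few abundant transcripts would shift the rest.

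The total expected count was 14605326 to 15219424 per library and differed little between libraries. A gene with no count in a library could have been present at up to 3 counts, or 0.197 to 0.205 CPM (the count scaled to library size, in the usual unit); such limits and the intervals on count ratios cover counting error only, because the sources used here name no molecular identifiers. Replicate libraries of each group differed by more than sampling noise (chi-square over degrees of freedom 14.5 to 76.9), so none was treated as a repeat of another.

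Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood F test). All 6 libraries entered a fit with the group as its only term, and a gene was called changed at a two-sided Benjamini-Hochberg adjusted p under 0.05. Of the 9834 genes, 8336 passed the filter and were tested; 176 had no count in any library. The standard error of a log2 fold change was approximated by its size divided by the square root of the F statistic. For genes with few counts in a group, such as POX01175, this approximation can fall below counting error alone. A fold change of a gene at 0 in every library of a group was bounded with a floor of 3 counts over that group. For the named genes, an exact two-sided permutation test of the 6 FPKM values was added; with 3 libraries against 3 it cannot go below p = 0.1. As a test on simulated data, counts were drawn from the real means, library sizes and dispersions for these 8336 genes. In them edgeR recovered 98 of 100 genes changed 4-fold and 74 of 100 genes changed 2-fold, and 8.51% of its calls were false. The simulated genes were independent, and fewer were changed than were called in the real data. The share of false calls there need not be the same.

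The design was written before the data were examined: FPKM alone was assumed, with edgeR as the main test should expected counts be present, as they were. The alternatives set then were edgeR without the low-count filter, edgeR with DESeq2 size factors, DESeq2 1.42.0, edgeR with the replicate letter as a block, limma 3.58.1 on log2(FPKM + 1) with genes kept at FPKM of at least 1 in at least 3 libraries, 10 variants of that limma fit, and 6 fits that each left out 1 library.

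Gene lists by function (cellulases, xylanases and 26 others) had been planned from product names. The files do not pair IDs with names. The reference table used here, made for assembly ASM172317v3 of strain HP7-1, gives newer locus tags without product names; none of the 9834 IDs equals a tag, older tag, synonym or symbol in it. Its tags carry 5-digit numbers, but at the same number the log gene lengths in the table and those implied by the counts and FPKM correlated across 7275 genes at only r = 0.0069, so numbers were not used to join them. The lists and their set tests, and all coordinates, were therefore left out. By the rule fixed for this case, the genes named are POX06509 and the 2 genes with the largest rise and the 2 with the largest fall among changed genes whose groups did not overlap and whose mean FPKM was at least 10 in the higher group. Any other gene or run of IDs named was chosen after its values were seen. Neighbouring ID numbers were compared with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.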

Results

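The data comprised 6 RNA-seq libraries of Penicillium oxalicum mycelium after 24 h in medium with cellulose, 3 of the POX06509 deletion mutant and 3 of the Ku70 mutant. The question was how loss of POX06509 changed gene expression, in a series about transcription factors that control cellulase and xylanase genes. Strain and deletion go together in this design, so loss of POX06509 cannot be told apart from other differences between the strains. The strain labels do not say whether the deletion mutant was made in the Ku70 mutant. Total expected counts were 14605326, 14923813 and 15081626 in deletion libraries F, S and T, and 15219424, 15022017 and 15203910 in Ku70 libraries F, S and T. Between 9249 and 9398 of the 9834 genes had at least 1 count in a library, and the 10 most abundant genes of each library took 9.52% to 10.6% of its counts. Correlations of log2(CPM + 1) across the 8336 tested genes were 0.982 to 0.995 within the deletion group, 0.983 to 0.990 within the Ku70 group and 0.945 to 0.975 between the groups. The first principal component, with 66.2% of the variance, separated the groups. On it Ku70 library S scored 12.3, against 30.1 and 33.1 for Ku70 libraries F and T and -26.3 to -24.3 for the deletion libraries.

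POX06509 itself was almost absent from the deletion libraries. They held 0, 0 and 1 counts of it in F, S and T, against 1405, 2580 and 1851 counts in Ku70 libraries F, S and T. Its FPKM was 0.0133 ± 0.0231 (SD, n = 3) in the deletion and 69.7 ± 21.8 (SD, n = 3) in the Ku70 mutant. The summed counts, scaled for library size, were 5592 times higher in the Ku70 mutant, with an exact 95% interval of 1003 to 220929 for counting error. The adjusted p for POX06509 from edgeR's quasi-likelihood test was 4.52e-07, and an exact two-sided permutation test gave p = 0.1, the smallest it can give. The same permutation p holds for the other 4 genes named by the fixed rule, since the groups did not overlap for any of them. The 6 genes tested among the 10 ID numbers nearest to POX06509 included 1 call, POX06508, named after its values were seen. POX06508 fell from 10.9 ± 1.195 FPKM (SD, n = 3) in the Ku70 mutant to 3.07 ± 0.632 FPKM (SD, n = 3) in the deletion, a log2 fold change of -1.78 ± 0.24 (SE) with an edgeR adjusted p of 0.000695.

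With the deleted gene included, the deletion differed from the Ku70 mutant in 1050 of 8336 tested genes (12.6%). Of these, 444 rose and 606 fell, POX06509 among the latter. The rises were larger than the falls: the median change was 2.79-fold among genes that rose and 1.97-fold among genes that fell. Changes of at least 2-fold were found for 298 genes that rose and 286 that fell, and changes of at least 8-fold for 66 that rose and 8 that fell. The 8-fold counts depended on the scale: in limma on log2(FPKM + 1), where the pseudocount shrinks the change of low genes, 22 rose and 3 fell by that much (POX06509, POX09352 and POX05360), while 3 rose (POX01168, POX01175 and POX07772) and 1, POX06509, fell with a pseudocount of 5. With a pseudocount of 0.1, limma gave 58 that rose and 8 that fell by at least 8-fold. Of the 444 genes that rose, 9 had 3 or fewer counts over all 3 Ku70 libraries. The calls used edgeR's quasi-likelihood test at an adjusted p under 0.05. The values of the groups did not overlap for 1035 of the 1050 called genes and for 31.1% of all tested genes, where chance gives 10% for 3 libraries against 3. The count of calls rested on single libraries: 1031 genes rose and 1109 fell without Ku70 library S, and 286 rose and 306 fell without Ku70 library F. Without Ku70 library T 295 rose and 273 fell, and without deletion library T 331 rose and 331 fell, so the excess of falls over rises was not kept in either.

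**Figure D1:**
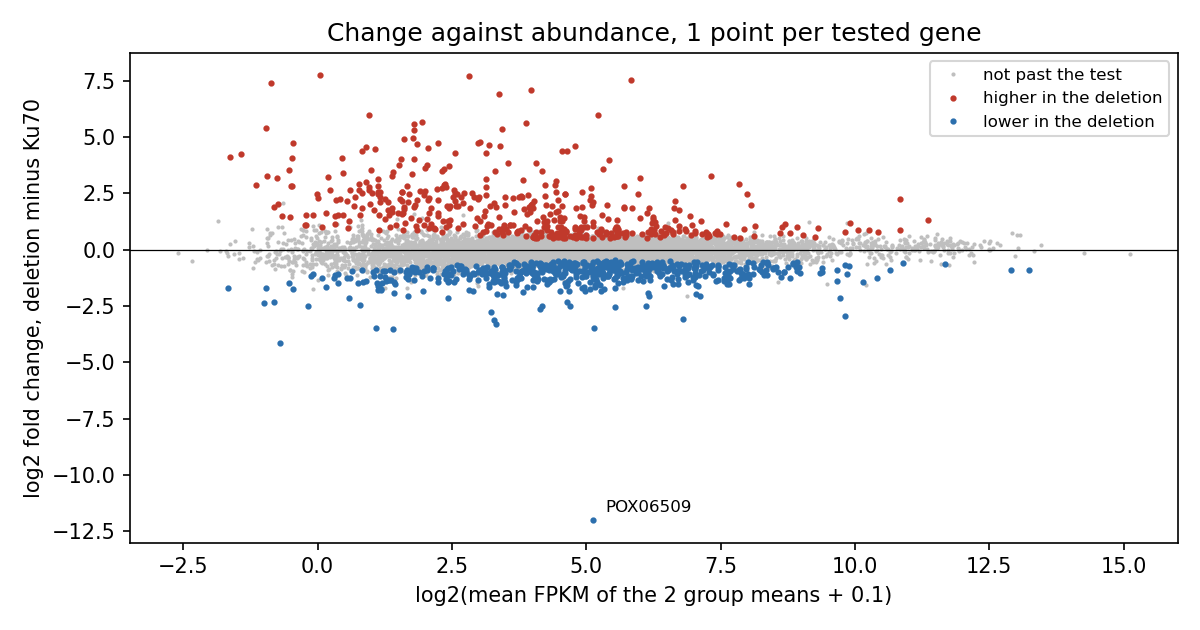
Each point is a tested gene; the x axis is the log2 of the mean of both groups' FPKM plus 0.1 and the y axis the fitted log2 fold change, deletion minus Ku70. Red points are the 444 genes that rose and blue points the 606 that fell; apart from POX06509, the points farthest from 0 are genes that rose.

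Among the 1000 most abundant genes, ranked by their mean over all 6 libraries, 33 rose and 91 fell. Among the other tested genes 411 rose and 515 fell. Falls were thus a larger part of the calls among abundant genes (odds ratio 2.20, two-sided Fisher's exact test across genes, which are not independent, p = 0.000148). This grouping was chosen after the data were seen, and its direction turned without Ku70 library S, where 147 of the abundant genes rose and 123 fell, and with limma's array weights, where 265 rose and 208 fell. Among the abundant genes 20 rose and 69 fell without deletion library S, 18 and 59 without deletion library T, 12 and 57 without Ku70 library F, and 15 and 54 without Ku70 library T, while DESeq2 called 57 that rose and 110 that fell.

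The ranking took called genes with a mean FPKM of at least 10 in the higher group and no overlap between the groups. Its largest rises in the edgeR fit were of POX01180 and POX01175, both close to silent in the Ku70 mutant. Limma on log2(FPKM + 1) gave them log2 changes of 3.83 and 6.15, so their order rests on the fit. POX01180 had 91, 95 and 90 counts in deletion libraries F, S and T and a single count over the Ku70 libraries, in F. Its FPKM was 13.9 ± 0.447 (SD, n = 3) in the deletion and 0.050 ± 0.087 (SD, n = 3) in the Ku70 mutant, and its scaled counts were 288 times higher in the deletion (exact 95% interval 51.3 to 11417 for counting error). The edgeR adjusted p for POX01180 was 7.22e-06. POX01175 rose from 0.610 ± 0.080 FPKM (SD, n = 3) to 113.3 ± 12.4 FPKM (SD, n = 3), a log2 fold change of 7.55 with an edgeR adjusted p of 1.96e-08. Its scaled counts were 190 times higher in the deletion (exact 95% interval 124 to 308 for counting error). The largest falls among genes chosen in the same way, after that of POX06509, were of POX09352 and POX08890. POX09352 fell by 3.49 ± 0.69 (SE) on the log2 scale, from 64.7 ± 59.8 FPKM (SD, n = 3) in the Ku70 mutant to 5.52 ± 4.38 FPKM (SD, n = 3) in the deletion, with an edgeR adjusted p of 0.0072. Its Ku70 values were 43.4, 18.5 and 132.3 FPKM in F, S and T, and the log2 fold change was -2.47 without Ku70 library T and -4.34 without deletion library S. POX08890 fell by 3.30 ± 0.39 (SE) on the log2 scale, from 18.0 ± 6.73 FPKM (SD, n = 3) to 1.76 ± 0.931 FPKM (SD, n = 3), with an edgeR adjusted p of 0.000295. The log2 changes are fitted values with approximate errors, and the functions of these 4 genes are not given in the sources used here.

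**Figure D2:**
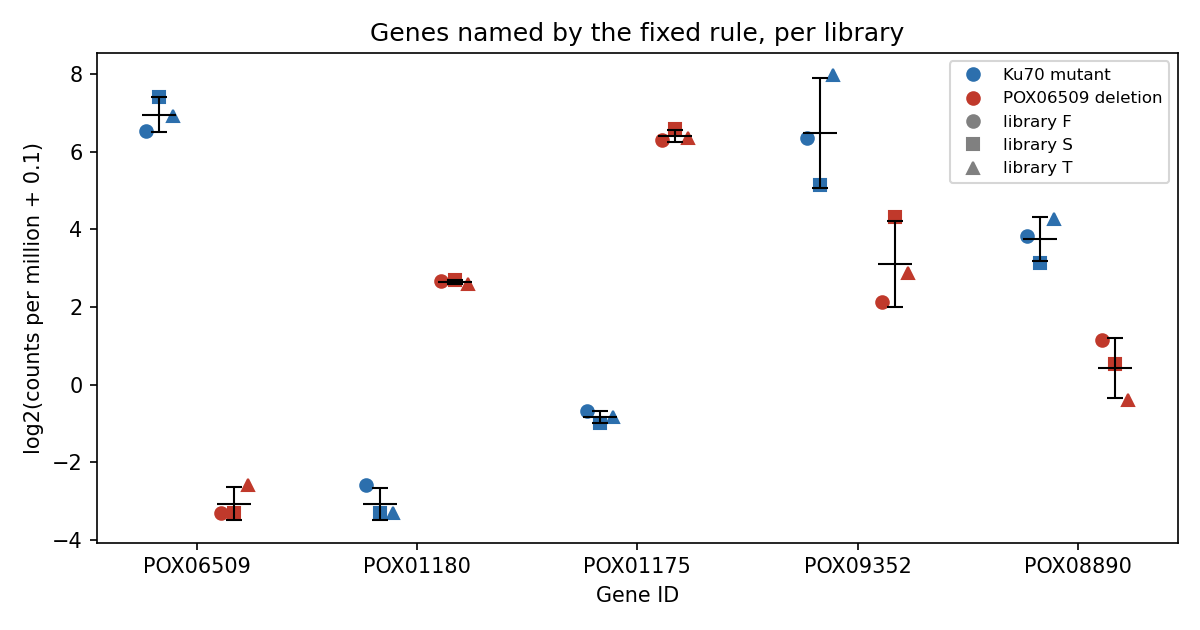
Log2(CPM + 0.1) (y axis) of the 5 genes named by the fixed rule (x axis) in each library; blue is the Ku70 mutant, red the POX06509 deletion, the marker shape gives the library letter, and black bars are the mean and SD of 3 libraries. The groups do not overlap for any of the 5 genes, and the 3 Ku70 libraries are farthest apart for POX09352.

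Of the 444 genes that rose, 80 lay in runs of at least 4 consecutive ID numbers. POX01175 and POX01180 belonged to 18 consecutive IDs, POX01167 to POX01184, that all rose. POX01178 in this run had 78 counts over the deletion libraries and 0 in every Ku70 library, a log2 change of at least 4.76 against a floor of 3 counts over the Ku70 group. With POX01178 at that bound, the log2 changes of the 18 genes ran from 1.83 to 7.70 with a median of 5.17, and with its fitted value the median was 5.60. The median FPKM of these 18 genes was 0.655 in the Ku70 mutant and 19.1 in the deletion. Their summed counts were 9197 ± 1528 (SD, n = 3) per deletion library and 871.3 ± 80.4 (SD, n = 3) per Ku70 library. A second series of 15 consecutive IDs, POX05852 to POX05866, also rose throughout, with log2 fold changes of 1.53 to 5.35 and a median of 4.01. Its summed counts were 2240 ± 393.5 (SD, n = 3) per deletion library and 278 ± 57.2 (SD, n = 3) per Ku70 library. In all, 88 called genes lay in 13 runs of at least 4 consecutive IDs called in the same direction, 80 of them in 11 runs that rose and 8 in 2 runs that fell. Limma called 14 genes in such runs, at most 6 in a run, among genes with a mean FPKM of at least 5, and 286 with array weights. With its filter of FPKM of at least 1 in 3 libraries the longest run had 10 genes, and without a filter 18. A run ended at any ID that was not tested, so a filter on low values can shorten runs by itself. Both long runs and POX01178 were named after their values were seen, and whether ID numbers follow positions on the chromosomes is not given in the sources used here.

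**Figure D3:**
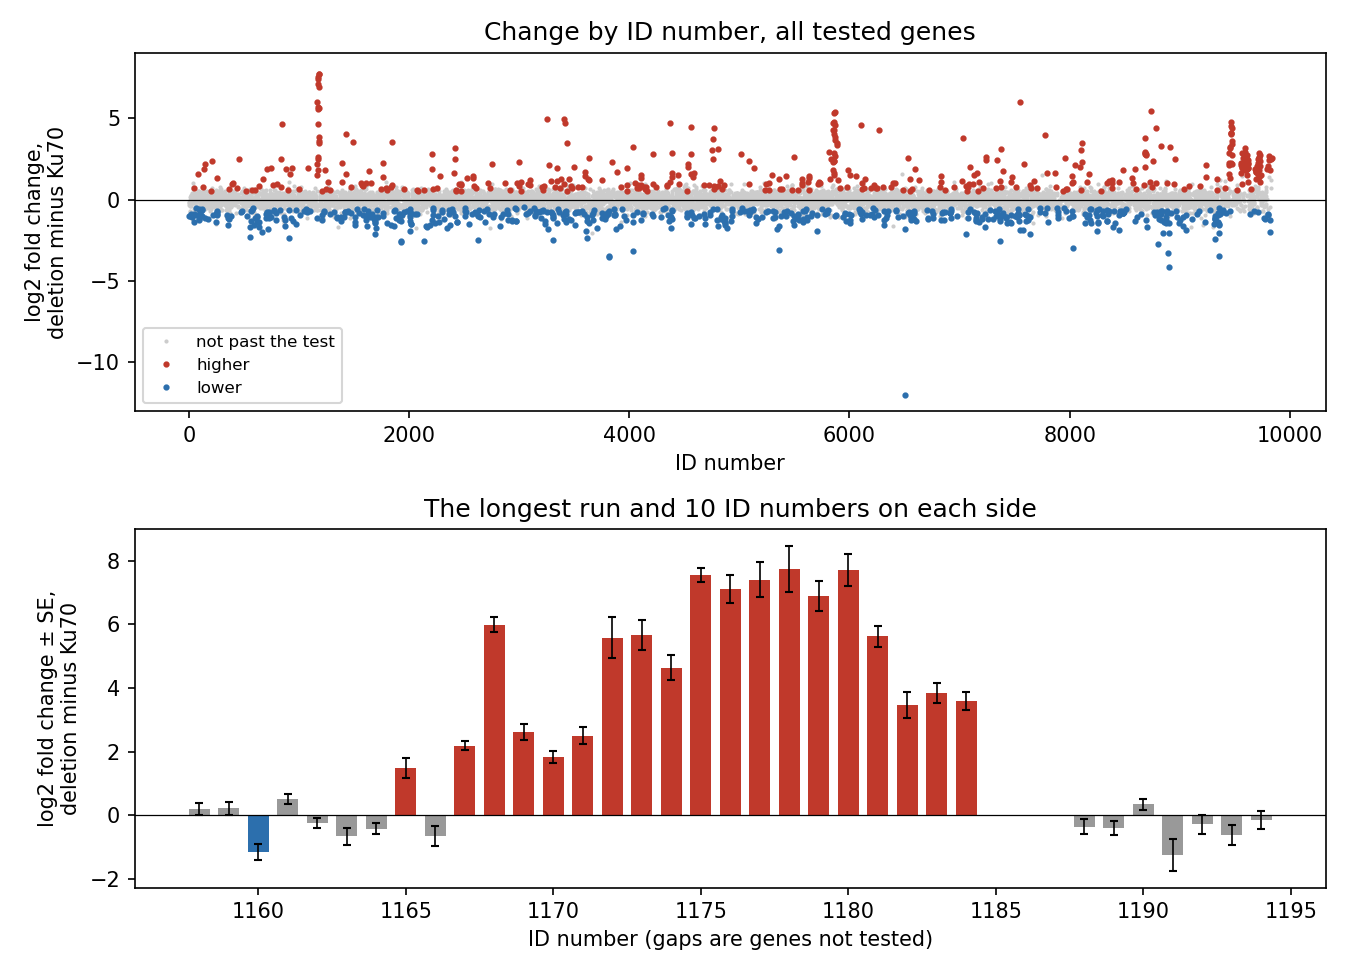
Top: fitted log2 fold change, deletion minus Ku70 (y axis), of all tested genes by ID number (x axis), with genes that rose in red, genes that fell in blue and others in grey. Bottom: the same value for the run of 18 genes and 10 ID numbers on each side, with error bars of 1 approximate SE. These error bars can be too short for genes with few counts in the Ku70 libraries. All 18 genes rose, the lowest by 1.83 on the log2 scale. The fitted bar of POX01178, at 0 in every Ku70 library, is not a bound.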

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

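POX06509, POX01180, POX01175, POX09352 and POX08890 kept their direction and an adjusted p under 0.05 in all 21 alternatives; the adjusted p of POX09352 ranged from 2e-10 (edgeR with the letter as a block) to 0.0351 (limma without the filter on low values), the largest of any of the 5. The counts were less stable. Whether the letters pair the libraries is not settled. Same-letter deviations correlated at 0.39 for F, 0.063 for S and 0.054 for T. Only deletion library F correlated best with the Ku70 library of its own letter, and at most at -0.11 with the others. A batch shared by the F libraries thus cannot be excluded, and the main fit would leave it out. With the letter as a replicate block, edgeR called 1972 genes, 898 higher and 1074 lower, including all 1050 of the fit without it. Among the 1000 most abundant genes the block gave 94 higher and 129 lower in edgeR and 58 higher and 125 lower in limma. With array weights, limma called 3650 genes, 1620 higher and 2030 lower; the cause was not tested. Limma on genes with a mean FPKM of at least 5 called 267 higher genes, and 352 genes changed at least 2-fold, with fewer genes tested (7052). A pseudocount of 5, which shrinks the change of low genes, left 284 genes changed at least 2-fold. Leaving out 1 library gave 568 to 2140 changed genes, 286 to 1031 higher and 273 to 1109 lower. The other settings stayed within 1.5 times of the 1050, 444, 606 and 584 calls, and DESeq2 called 1386 genes. Of the 1050 genes, 862 were also called by limma on log2(FPKM + 1) and 1035 by DESeq2. Genes higher by at least 8-fold numbered 63 to 70 without 1 library. In limma they numbered 58, 22 and 3 with pseudocounts of 0.1, 1 and 5. Those lower by at least 8-fold numbered 8 in the main fit, and 8, 3 and 1 in these limma fits. The set tests for cellulases, xylanases and other lists, with their camera and fry alternatives, were not run, since no table used here names the genes. Depth limits the folds of genes at 0 to 3 counts, such as POX01180, whose fitted log2 change, set by the prior count there, was 9.55 without Ku70 library F, the library holding its only Ku70 count.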

Other observations

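The tests in this part were chosen after the results were seen, except the count of other splits of the libraries. Of 318 tested genes with ID numbers above 9400, 83 rose (26.1%) and 11 fell, and 4.50% of the tested genes with numbers up to 9400 rose. Over the 21 alternatives the shares that rose were 17.5% to 40.7% and 2.67% to 18.5%, the first above the second in each alternative. The number above 9400 that fell was 5 without deletion library T, 7 without Ku70 library F, 6 without Ku70 library T and 25 without Ku70 library S, and up to 52, with limma's array weights, over the alternatives. Of the 11 runs of at least 4 consecutive IDs that rose, 7 lay in this range, with 38 genes. The split at 9400 was set after the values were seen, and the difference was not tested.

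Fitted log2 changes correlated between adjacent ID numbers, with r = 0.3984 (Spearman 0.17) across 7294 pairs of genes, which are not independent replicates. Over the alternatives r was 0.2345 to 0.4305, and in the main fit it was 0.19 without the genes in runs. Part of the correlation is not particular to the strains. On log2(CPM + 1), 1 library against the others of its own group gave 0.068 to 0.12, where the strains gave 0.31. On the scale of the fitted changes, where the strains gave 0.3984, each of the 9 splits that mix the strains, which keep part of the strain difference, gave less, 0.12 to 0.32. A chance order of the IDs is argued against by a permutation test, in which 100000 reassignments of the changes gave r of at most 0.0557 (p = 1e-05, the smallest they can give). Reads shared between adjacent or near-identical genes are argued against as the only cause. Between genes with whole counts in every library, r was 0.254 at a distance of 3 numbers. The genes in runs are part of this value, and shared reads may still add to the adjacent r. A single change in copy number over the run of 18 genes is argued against by the scatter of its log2 changes, were expression proportional to copy number. Its chi-square over degrees of freedom was 55.2. Low counts do not explain this scatter: POX01167, with 836 Ku70 counts, rose by 2.19, and POX01168, with 94, by 5.99. Over 7 of the other 12 runs the values were at least 3.40, with 18.9 for the run of 15 genes. Over the remaining 5 they were at most 2.35 (smallest adjusted p of the chi-square test 0.102). The approximate errors can be too small for genes with few counts, which raises these values. A single change therefore cannot be told apart in the 5 runs, nor at low values such as 3.40. A hypothesis for the 11 runs that rose, and not for the 2 that fell, is that they may be neighbouring genes kept low when POX06509 is present; the positions of the genes and binding of POX06509 at them, which would decide it, were not used here, so it was not tested.

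For the 605 genes other than POX06509 that fell, Ku70 library S lay nearer to the deletion than Ku70 libraries F and T did. Shares were put on a scale of CPM from 0 at the mean of the other Ku70 libraries to 1 at the mean of the deletion. The median was 0.46 in S (95% interval of a bootstrap over genes 0.42 to 0.48), -0.149 in F and -0.418 in T. On log2(CPM + 1) it was 0.35, -0.133 and -0.319. The genes are not independent and S is a single library, so the interval does not measure spread between libraries. For the 444 genes that rose the median was 0.040 in S and -0.031 in both F and T on the CPM scale. There a spread between Ku70 libraries gives larger values for genes that fell than for genes that rose, so these sizes are not compared. On log2(CPM + 1) the genes that rose gave 0.093 in S, -0.051 in F and -0.055 in T. Ku70 library S thus lay nearer to the deletion for these genes too. Both sets were called with S among the Ku70 libraries, and without it 1031 genes rose and 1109 fell. Genes for which S lay near the deletion may thus be missing from either set. The sizes on this scale, 0.35 and 0.093, are therefore not compared either. Admixture of deletion RNA or reads would move the CPM of every changed gene by the same share. For the 66 genes that rose at least 8-fold the median in S was 0.0035 (95% interval of the bootstrap over genes -0.00517 to 0.0131). Their choice used S among the Ku70 libraries, which by itself keeps this share low. The 298 genes that rose at least 2-fold, whose fold bounds the share far less, gave 0.0099 (0.0020 to 0.026). Their call also used S and may leave out genes with a high share, so this value does not decide on admixture. POX06509 argues against admixture, as it was higher in S (178.2 CPM) than in F (90.4 CPM) or T (115.8 CPM). A shallow library is argued against by its total of 15022017 counts, within the range of the others. A difference between cultures in growth or harvest may remain open, and no biological explanation was tested.

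The real grouping gave 1050 calls in edgeR's quasi-likelihood test, and each of the other 9 of the 10 splits into 3 and 3 gave 0, so 1 of the 10 splits gave as many. With 10 splits the share cannot fall under 0.05. At an unadjusted p under 0.05 the real grouping gave 2439 genes and the others 23 to 1787, and only edgeR was run on the splits. The split with 1787 set deletion library F and Ku70 libraries F and T against deletion libraries S and T and Ku70 library S.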
